A study of Mus musculus with 14 samples.

How the data were processed

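RNA of sorted splenic CD4 T cells was sequenced from 7 mice, 4 B6 and 3 TC, with a Tfh and a Tn library from each, giving 14 libraries in 4 groups. Tfh were gated as CD44-positive, CD162-low or negative and PD-1-positive, and Tn as CD44-negative, per the labels. These gates did not exclude regulatory T or follicular regulatory cells. Libraries were made with a TruSeq Stranded kit from column-purified RNA, per the labels' protocols. The source label of the Tn samples names Tfh, and their titles and gates name Tn, so the titles were followed.

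The deposited table holds read counts, 1 column per library and 1 line per gene symbol. Reads were aligned with STAR 2.7 to mm10 and tested with DESeq2, per the submitters' processing notes. The counting tool, its strand setting and the annotation behind the symbols are not given in the sources used here. Counts of antisense, overlapping and closely similar genes are therefore uncertain. The reference genome is of the B6 strain, and counts of TC genes whose sequence differs from it were not corrected for alignment. Sequencing batch is not in the labels.

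All 26683 symbols were read and no column was left unused. Library totals ran from 15162309 to 20191558 counts. A floor of 3 counts is 0.198 CPM in the smallest and 0.149 CPM in the largest library. Where a group had no counts, a fold is given as at least the ratio to a floor of 3 counts over the whole group, and where it had 1 to 3, as a ratio with an exact 95% counting interval. These floors and intervals cover counting error only and not the spread between mice. Other folds carry no interval. Where they rest on Tn levels below the floor of a single library, as for Il21, Ifng and Pax5 in B6, they are imprecise. No pair of libraries within a group differed as little as duplicates would (chi-square per degree of freedom 5.31 to 20.4).

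CPM values and tests were computed from these counts. Genes passed filterByExpr at a count minimum of 10 (13427 genes), were normalized by TMM and fitted with edgeR 4.0.16 (robust quasi-likelihood, a mean for each of 4 groups, no block) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The 5 comparisons were Tfh against Tn in each strain, TC against B6 in each cell type, and the interaction of strain and cell type. Positive values of the interaction mean a higher Tfh to Tn ratio in TC.

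Of 38 gene lists fixed beforehand, 32 had at least 5 members tested. These were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with its preset correlation of 0.01 between genes, and adjusted over the lists. Camera compares a list with the other genes, so its direction is relative to them. Counts of called members are given with adjustment over all genes tested and, beside them, adjusted over the list alone. A gene without overlap had every library of a group above every library of the other.

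The design, gene lists, comparisons, naming rule and first set of alternatives were chosen before the data were examined. The naming rule took the 6 largest rises and falls past the threshold with a mean of at least 5 CPM and no overlap, leaving out receptor segments, unnamed and pseudogene-like loci and sort markers. It added up to 4 members per described list with the smallest adjusted p, and a fixed set of helper, metabolic and sort genes. Results for a few of these genes are not reported here. Gene positions and transcript lengths came from GENCODE M21, whose genome build is that of mm10. By symbol 24746 genes matched, 611 by synonym, 1284 not at all and 42 ambiguously. Lengths were found for 13145 of the genes tested (97.9%).

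Replicate numbers mark the mouse within a strain, since the protocol sorts Tfh and Tn from the spleen of each mouse. Deviations from group means of same-numbered Tfh and Tn libraries correlated at 0.299, 0.114, 0.039 and 0.203 in B6 and 0.209, 0.207 and 0.257 in TC. Of 14 libraries 12 correlated best with their own mouse, and neither library of B6 mouse 3 did. A fit with mouse as a block was run as an alternative. Its consensus correlation in limma voom was 0.225.

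Alternatives tried were DESeq2 1.42.0, limma voom with mouse as a random effect, RLE size factors, TMM without receptor segments and mitochondrial genes, no filter or a count minimum of 50, legacy quasi-likelihood, only the groups compared, a fold above 2, the block, and each library left out in turn. List tests were repeated with an estimated correlation and with fry, which tests each list against no change rather than against other genes. Corrections for transcript length and GC, splines of 5 degrees of freedom for each library fitted on all genes or on genes of at least 5 CPM, were added after seeing the data.

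The fit was tested on simulated data with 200 changed genes. Libraries were simulated without pairing by mouse, and far fewer genes changed than were called between cell types or strains in the data. It recovered 62.5, 45.6, 60.3, 53.3 and 38.2% of 1.5-fold changes in the 5 comparisons, 80.3, 70.9, 69.6, 85.9 and 65.8% of 2-fold, and 98.6, 94.3, 94.3, 93.4 and 90.6% of 4-fold. Of its calls 5.75, 5.52, 5.19, 1.94 and 5.26% were false. A simulated length trend gave 814 false calls before and 0 after either length correction. That trend was linear in log2 length, which the correction can fit, and no gene changed otherwise. It therefore does not show how far the correction spares real differences.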

Results

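CD4 T cells were sorted from the spleens of 8-month-old female mice of 2 strains: C57BL/6J (B6) and triple congenic (TC) mice, which carry the lupus susceptibility intervals Sle1, Sle2 and Sle3 on the B6 background. Those intervals lie on chromosomes 1, 4 and 7. From each mouse came CD44-positive, CD162-low, PD-1-positive cells (Tfh) and CD44-negative naive cells (Tn). The data held 4 B6 Tfh, 4 B6 Tn, 3 TC Tfh and 3 TC Tn libraries from 4 B6 and 3 TC mice. Counts were given for 26683 gene symbols, and 13427 genes were expressed highly enough to test. Values of the form a ± b are means ± SD in CPM, counts per 1e6 counts of the library, over 4 B6 or 3 TC libraries.

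Transcripts of the proteins used for sorting separated the populations in both strains. Pdcd1, which encodes PD-1, stood at 661 ± 68.8 CPM in B6 Tfh and 8.41 ± 1.85 in B6 Tn, and at 472 ± 88.0 in TC Tfh and 5.71 ± 1.31 in TC Tn. Cd44, the adhesion receptor of antigen-experienced cells, stood at 391 ± 13.7 and 26.8 ± 2.98 CPM in B6, and at 356 ± 14.96 and 19.5 ± 2.26 in TC. Selplg, which encodes CD162, was the lower in Tfh, at 142 ± 26.8 against 657 ± 48.3 CPM in B6 and 112 ± 14.4 against 510 ± 17.9 in TC. In the principal component map the first component held 80.5% of the variance and parted Tfh from Tn, and the second held 11.4% and parted the strains. These sort-marker contrasts describe the gates and are not findings of the comparisons below.

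**Figure D1:**
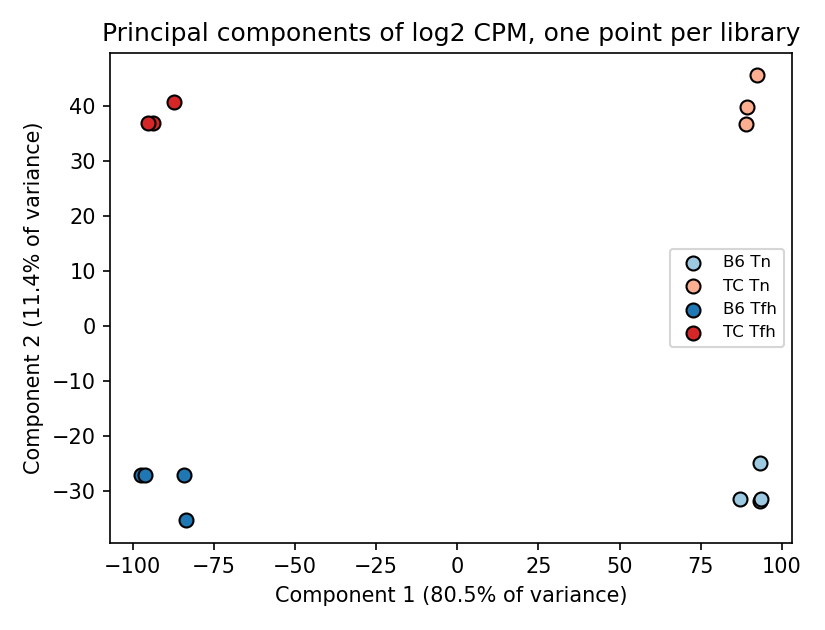
Principal components of the 14 libraries, from log2 CPM of the genes tested. Points are single libraries. Colours mark strain and cell type.

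Cell composition and library quality were measured alongside. Ribosomal protein genes took 4.03 ± 0.464% of counts in B6 Tfh, 8.70 ± 0.583% in B6 Tn, 2.91 ± 0.0379% in TC Tfh and 6.32 ± 0.306% in TC Tn. The noncoding transcript Gm26917 took 0.00441 ± 0.00114%, 0.00862 ± 0.00265%, 0.0404 ± 0.00854% and 0.0509 ± 0.0109% in the same order. Immunoglobulin genes took 0.213% in B6 Tfh and 0.215% in TC Tfh, against 0.0591% and 0.0736% in Tn.

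In B6 mice, Tfh cells carried far higher levels than Tn cells of the follicular helper programme. Tox2, a transcription factor of the Tfh lineage, rose 359-fold, from 0.85 ± 0.358 to 304 ± 29.9 CPM (log2 fold change 8.49, SE 0.13, adjusted p = 7.31e-18). Cxcr5, the follicle-homing chemokine receptor, rose 67.8-fold to 622 ± 13.8 CPM (adjusted p = 3.37e-14), and Bcl6, the lineage-defining repressor, 6.18-fold to 221 ± 24.7 CPM (adjusted p = 9.31e-12). Il21, the helper cytokine, rose 1610-fold to 191 ± 25.2 CPM (adjusted p = 1.83e-16). Il4, with no counts in B6 Tn, rose at least 195-fold to 8.18 ± 0.585 CPM (adjusted p = 3.34e-11).

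Other members of the Tfh identity list rose with them. P2rx7, a receptor for extracellular ATP, rose 10.1-fold to 346 ± 22.8 CPM (adjusted p = 7.7e-16), Angptl2 420-fold to 455 ± 42.4 CPM (adjusted p = 4.58e-15), and the costimulatory receptor Icos 7.51-fold to 444 ± 60.0 CPM (adjusted p = 2.74e-13). Of 27 Tfh identity genes tested, 25 rose and 1 fell (adjusted over the list alone, 26 and 1), with a list test adjusted p = 4.87e-11, and adjusted p = 0.0956 with an estimated correlation. The largest rises at 5 CPM or more, outside receptor segments, included Spp1, encoding osteopontin (at least 1640-fold, to 68.8 ± 12.3 CPM, adjusted p = 1.13e-07), Lrrn3 (at least 407-fold, to 17.1 ± 2.21 CPM, adjusted p = 8.5e-12) and Kirrel3 (at least 272-fold, to 11.4 ± 3.57 CPM, adjusted p = 2.13e-07). Ecel1, with 1 count over all B6 Tn libraries, rose to 62.8 ± 17.4 CPM, a ratio of 4500 (95% counting interval 807 to 178000, adjusted p = 6.31e-12). Sostdc1, a secreted BMP and Wnt antagonist, rose 1940-fold to 311 ± 74.0 CPM (adjusted p = 4.86e-10).

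The naive programme fell. Igfbp4, an IGF-binding protein, fell 785-fold, from 1422 ± 139 to 1.80 ± 0.194 CPM (log2 fold change −9.62, SE 0.11, adjusted p = 7.47e-20). Lef1, a transcription factor of naive T cells, fell 7.08-fold to 139 ± 14.9 CPM (adjusted p = 4.55e-16) and Ccr7, the chemokine receptor for T cell zones, 7.94-fold (adjusted p = 1.58e-13). Cd55, a complement regulator, fell 17.2-fold (adjusted p = 8.25e-16) and Txk, a Tec-family kinase, 12-fold (adjusted p = 1.21e-15). Other large falls were Pdlim4 (376-fold, from 60.4 ± 5.25 CPM, adjusted p = 8.62e-18), the AMP deaminase Ampd1 (332-fold, from 27.8 ± 5.27 CPM, adjusted p = 2.48e-15), Ly6c1 (236-fold, from 77.3 ± 10.1 CPM, adjusted p = 1.97e-15), Sorcs2 (146-fold, adjusted p = 4.68e-12) and Adamts14 (142-fold, adjusted p = 2.6e-16). Ly6c1 is nearly identical in sequence to Ly6c2, so its counts are uncertain. In the naive and quiescence list 26 of 28 genes fell and none rose (the same over the list alone), with a median log2 fold change of −2.19, list test adjusted p = 2.65e-11, and adjusted p = 0.0956 with an estimated correlation.

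Genes of other T cell programmes were also higher in B6 Tfh. The gate did not exclude regulatory T or follicular regulatory cells, and how far such cells account for this was not tested. All 18 Treg and Tfr genes rose, with a median log2 fold change of 3.21 (list test adjusted p = 1.88e-07, and adjusted p = 0.108 with an estimated correlation). Among them, Foxp3, the regulatory lineage factor, rose 8.26-fold to 311 ± 37.0 CPM (adjusted p = 3.85e-10), Ikzf2, encoding Helios, 51.6-fold to 784 ± 121 CPM (adjusted p = 4.25e-14), Nrp1 75.6-fold (adjusted p = 2.41e-13) and Tnfrsf4, encoding OX40, 14-fold (adjusted p = 1.18e-14). In the Th1 and cytotoxic list 17 of 22 rose and 3 fell (adjusted p = 0.00255, and adjusted p = 0.404 with an estimated correlation), with Tbx21, encoding T-bet, up 85.7-fold (adjusted p = 1.96e-14), Il12rb1 8.54-fold (adjusted p = 2.24e-14) and Ifng 188-fold to 22.4 ± 2.76 CPM (adjusted p = 1.19e-12). In the Th17 list 6 of 7 rose (adjusted p = 0.0099, and adjusted p = 0.144 with an estimated correlation), Rora 7.31-fold (adjusted p = 2.41e-13) and Ahr 7.24-fold (adjusted p = 1.57e-10) among them. In the Th2 list 5 of 6 rose and 1 fell (adjusted p = 0.0733). Il10, an anti-inflammatory cytokine, rose to 3.14 ± 0.973 CPM (adjusted p = 4.75e-06), where Tn held 4 counts, all in B6 Tn 2. Counts adjusted over the list alone were the same for these 4 lists.

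Inhibitory receptor and senescence genes rose as lists, and their tests held with an estimated correlation. Of 18 inhibitory receptor and exhaustion genes 16 rose, with a median log2 fold change of 2.90 (adjusted p = 2.94e-06, and adjusted p = 0.0311 with an estimated correlation). They included the ectoenzymes Cd38 (46.1-fold, adjusted p = 1.6e-15) and Entpd1 (23-fold, adjusted p = 1.74e-14) and the transcription factor Nfatc1 (4.36-fold to 959 ± 40.9 CPM, adjusted p = 1.28e-15). Of 15 senescence genes 13 rose and 2 fell (adjusted p = 0.000518, and adjusted p = 0.0311 with an estimated correlation). Among those were Cebpa (602-fold to 114 ± 17.8 CPM, adjusted p = 4.58e-15), Tnfsf11, encoding RANKL (31.6-fold, adjusted p = 4.68e-15), the growth factor Csf1 (50.3-fold, adjusted p = 1.54e-13) and the cell cycle inhibitor Cdkn2c (5.85-fold, adjusted p = 7.14e-13). Over the list alone both counts were the same.

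Among metabolic genes in B6, Hmgcs1, Srebf2 and Mvd of sterol synthesis were lower in Tfh. In the fatty acid and cholesterol synthesis list 22 of 30 fell and 4 rose (median log2 fold change −0.71, adjusted p = 4.46e-05, and adjusted p = 0.244 with an estimated correlation), with Hmgcs1, an early enzyme of the mevalonate pathway, down 2.78-fold (adjusted p = 2.79e-12), its regulator Srebf2 1.88-fold (adjusted p = 3.13e-11) and Mvd 4.15-fold (adjusted p = 3.16e-11). In the nuclear oxidative phosphorylation list 33 of 72 fell and 5 rose (33 and 4 over the list alone; median −0.13, adjusted p = 0.00379, and adjusted p = 0.613 with an estimated correlation), including Uqcrfs1 (1.72-fold, adjusted p = 1.33e-10) and Ndufa10 (1.62-fold, adjusted p = 2.47e-10). In the TCA cycle list 14 of 25 fell and 1 rose (adjusted p = 0.0103, and adjusted p = 0.459 with an estimated correlation), with Idh2 down 2.88-fold (adjusted p = 3.72e-13) and Pdha1, of pyruvate dehydrogenase, 1.59-fold (adjusted p = 1.27e-09). In the one-carbon and nucleotide list 16 of 23 fell and 5 rose (adjusted p = 0.0234, and adjusted p = 0.274 with an estimated correlation), including the purine enzymes Impdh2 (1.8-fold, adjusted p = 1.26e-11) and Gart (1.86-fold, adjusted p = 1.87e-11). Except where given, counts over the list alone were the same.

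Glycolysis genes moved both ways in B6: 16 of 27 rose and 8 fell (adjusted p = 0.278). Hif1a, the hypoxia-inducible regulator, rose 5.83-fold to 931 ± 112 CPM (adjusted p = 6.99e-13) and Hk2, a hexokinase, 9.16-fold to 6.60 ± 1.33 CPM (adjusted p = 8.08e-10), while Pdk1, which restrains pyruvate dehydrogenase, fell 6.86-fold (adjusted p = 4.36e-14), Myc 3.68-fold (adjusted p = 1.45e-10) and the lactate dehydrogenase Ldha 1.5-fold, from 601 ± 38.3 to 402 ± 36.2 CPM (adjusted p = 9.92e-07). The glucose transporter Slc2a1 did not pass (log2 fold change 0.16, adjusted p = 0.106; 0.0183 without B6 Tfh 1). In the pentose phosphate list 8 of 10 fell and 1 rose (adjusted p = 0.0613, and 0.0426 with mouse as a block). For fatty acid oxidation 11 of 23 rose and 5 fell (adjusted p = 0.37), for glutamine and glutamate metabolism 7 of 18 rose and 10 fell (adjusted p = 0.407), and for amino acid transport and mTORC1 7 of 26 rose and 8 fell (adjusted p = 0.534). For the latter pair the mean log2 fold change was above 0 while the test pointed down. None of 7 mitochondrial genome genes was called (adjusted p = 0.534). These counts were the same over the list alone.

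Proliferation and B cell genes were higher in B6 Tfh, and interferon-stimulated genes lower. Of 40 cell cycle genes 26 rose and 9 fell (26 and 10 over the list alone; adjusted p = 0.0103, and adjusted p = 0.23 with an estimated correlation), among them Mki67, a marker of cycling cells (15.9-fold to 44.5 ± 7.92 CPM, adjusted p = 4.63e-12), the replication helicase gene Mcm6 (2.53-fold, adjusted p = 1.58e-13) and the spindle kinesin Kif15 (25.5-fold, adjusted p = 1.66e-11). In the interferon-stimulated list 24 of 44 fell and 8 rose (adjusted p = 0.0152, and adjusted p = 0.611 with an estimated correlation), with Ifit2 down 2.68-fold (adjusted p = 2.55e-12), Ifit1 2.04-fold (adjusted p = 0.00168) and Oasl1 5.13-fold (adjusted p = 5.18e-10). In the B cell list 12 of 13 rose (adjusted p = 0.00185, and adjusted p = 0.277 with an estimated correlation), including Cd22 (293-fold to 92.2 ± 8.68 CPM, adjusted p = 1.35e-11), Pax5 (190-fold to 11.96 ± 3.76 CPM, adjusted p = 2.46e-11), Cd74 (8.03-fold, adjusted p = 2.76e-09) and Ighm (3.02-fold to 1789 ± 159 CPM, adjusted p = 2.41e-10). In the plasma cell list 10 of 12 rose (adjusted p = 0.00626, and adjusted p = 0.244 with an estimated correlation). The smallest adjusted p were those of Irf4 (14.5-fold, adjusted p = 6.1e-11) and Xbp1 (1.93-fold, adjusted p = 4.1e-10). Of 22 immediate early and stress genes 7 rose and 4 fell (adjusted p = 0.727), and of 14 Sle interval candidates 7 rose and 3 fell (adjusted p = 0.177). Other counts over the list alone were the same.

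Over all genes in B6, 9463 of 13427 changed between Tfh and Tn, 4975 up and 4488 down, and 15 of 32 list tests passed, 9 up and 6 down. No library of Tfh overlapped any of Tn for 8578 genes (63.9%), where chance gives 2.86%. The call on nuclear oxidative phosphorylation ended with correction for transcript length, a choice made after seeing the data (adjusted p 0.53 to 0.611 over its 3 forms).

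In TC mice the same programme separated Tfh from Tn. Tox2 rose 417-fold, from 0.79 ± 0.0784 to 334 ± 18.1 CPM (log2 fold change 8.70, SE 0.15, adjusted p = 8.7e-17), Cxcr5 83.1-fold to 415 ± 16.7 CPM (adjusted p = 3.42e-13), Bcl6 7.1-fold to 288 ± 40.7 CPM (adjusted p = 3.22e-11) and Il21 670-fold to 251 ± 28.7 CPM (adjusted p = 1.72e-15). Il4 rose 150-fold to 15.5 ± 2.93 CPM (adjusted p = 2.4e-11), Angptl2 363-fold (adjusted p = 4.87e-14) and Icos 6.12-fold (adjusted p = 8.26e-12). Igfbp4 fell 259-fold, from 741 ± 31.5 CPM (adjusted p = 7.07e-18), Lef1 6.56-fold (adjusted p = 1.05e-14), Ccr7 9.92-fold (adjusted p = 6.46e-13) and Cd55 17.1-fold (adjusted p = 6.37e-15).

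The largest rises in TC included genes without counts in TC Tn. Il9r, the interleukin 9 receptor, rose at least 385-fold to 22.3 ± 7.74 CPM (adjusted p = 1.2e-10), Rassf6 at least 255-fold (adjusted p = 1.11e-05), Tmem63c at least 249-fold (adjusted p = 1.23e-06), the integrin Itgb5 at least 219-fold (adjusted p = 9.86e-11) and Cd109 at least 212-fold (adjusted p = 3.08e-06). Ces2c, a carboxylesterase with 1 count in TC Tn, rose to 33.3 ± 4.47 CPM, a ratio of 1720 (95% counting interval 309 to 67900, adjusted p = 2.58e-17). Among falls, Lrrc75b had 2 counts in TC Tfh against 18.8 ± 0.912 CPM in Tn, a ratio of 488 (135 to 4030, adjusted p = 1.4e-14), and Adamts14 had 3 against 11.7 ± 1.28 CPM, a ratio of 203 (69.3 to 982, adjusted p = 1.06e-14). Pdlim4 fell 361-fold (adjusted p = 2.97e-15), the TGF-beta family receptor Acvrl1 202-fold (adjusted p = 2.2e-13) and Ampd1 183-fold (adjusted p = 1.07e-13).

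Helper, regulatory and naive lists moved the same way as in B6. Of 27 Tfh identity genes 25 rose and none fell (adjusted p = 7.49e-12, and adjusted p = 0.0723 with an estimated correlation), and of 28 naive genes 26 fell and none rose (median −2.28, adjusted p = 1.3e-11, and adjusted p = 0.0723 with an estimated correlation). All 18 Treg and Tfr genes rose (median 3.63, adjusted p = 5.95e-09, and adjusted p = 0.0723 with an estimated correlation), with Foxp3 up 12.4-fold to 324 ± 67.2 CPM (adjusted p = 6.14e-10), Ikzf2 60.8-fold to 1082 ± 54.3 CPM (adjusted p = 2.37e-13) and Tnfrsf4 12.9-fold (adjusted p = 2.45e-13). Of 22 Th1 and cytotoxic genes 14 rose and 4 fell (adjusted p = 0.0148, and adjusted p = 0.526 with an estimated correlation), with Ifng up 128-fold (adjusted p = 3.41e-12), Il12rb1 12.4-fold (adjusted p = 2.05e-13) and Il2rb, a receptor chain for interleukins 2 and 15, 18.1-fold to 741 ± 50.2 CPM (adjusted p = 2.77e-13). All 7 Th17 genes rose (adjusted p = 0.00619, and adjusted p = 0.101 with an estimated correlation), Rora 4.96-fold among them (adjusted p = 1.06e-11), and of 6 Th2 genes 5 rose and 1 fell (adjusted p = 0.0533). Il10 rose 51.1-fold to 15.3 ± 6.27 CPM (adjusted p = 8.36e-09). Counts over the list alone were the same.

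Inhibitory receptor and senescence lists again passed both tests. Of 18 inhibitory receptor genes 17 rose (adjusted p = 1.39e-06, and adjusted p = 0.0318 with an estimated correlation), among them Cd38 (75.8-fold to 40.2 ± 2.33 CPM, adjusted p = 1.17e-14) and Nfatc1 (4.59-fold, adjusted p = 1.09e-14). Of 15 senescence genes 12 rose and 2 fell (adjusted p = 0.000673, and adjusted p = 0.037 with an estimated correlation), with Tnfsf11 up 34.5-fold (adjusted p = 4.16e-14), Cebpa 375-fold (adjusted p = 2.23e-13), Csf1 42.8-fold (adjusted p = 1.19e-12) and Cdkn2c 30.9-fold to 10.3 ± 1.70 CPM (adjusted p = 5.23e-12). Over the list alone these were the same.

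Sterol synthesis genes fell in TC Tfh too. In the fatty acid and cholesterol synthesis list 25 of 30 fell and 2 rose (median −0.61, adjusted p = 2.76e-06, and adjusted p = 0.188 with an estimated correlation), with Hmgcs1 down 3.19-fold (adjusted p = 7.76e-12), Srebf2 2.13-fold (adjusted p = 3.32e-11) and Sqle, which commits squalene to sterols, 9-fold to 3.98 ± 0.624 CPM (adjusted p = 9.46e-11). In the TCA list 13 of 25 fell and 2 rose (13 and 1 over the list alone; adjusted p = 0.0304, and adjusted p = 0.565 with an estimated correlation), with Idh2 down 2.59-fold (adjusted p = 2.63e-11). In the nuclear oxidative phosphorylation list 30 of 72 fell and 7 rose (28 and 7 over the list alone; adjusted p = 0.0318, and adjusted p = 0.682 with an estimated correlation), with Ndufa10 down 1.59-fold (adjusted p = 5.74e-09). Of 23 one-carbon and nucleotide genes 14 fell and 5 rose (adjusted p = 0.0578, and 0.0475 with mouse as a block). In the mitochondrial genome 4 of 7 genes rose (5 over the list alone; adjusted p = 0.262), mt-Nd1 1.3-fold among them (adjusted p = 0.00248).

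Of 27 glycolysis genes in TC 14 rose and 8 fell (15 and 8 over the list alone; adjusted p = 0.315). Hif1a rose 7.82-fold (adjusted p = 1.37e-12) and Hk2 7.33-fold (adjusted p = 3.56e-07), and Pdk1 fell 5.11-fold (adjusted p = 3.99e-12), Myc 4.37-fold (adjusted p = 2.69e-10) and Ldha 1.51-fold (adjusted p = 7.06e-06). Slc2a1 did not pass (adjusted p = 0.875). For the pentose phosphate list 4 of 10 fell and 2 rose (adjusted p = 0.355), for fatty acid oxidation 13 of 23 rose and 4 fell (adjusted p = 0.286), for glutamine and glutamate 8 of 18 rose and 8 fell (adjusted p = 0.863), and for amino acid transport and mTORC1 5 of 26 rose and 8 fell (adjusted p = 0.602). The medians of the latter pair were above 0 while the tests pointed down.

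B cell genes were higher in TC Tfh as well: 11 of 13 rose (adjusted p = 0.000507, and adjusted p = 0.274 with an estimated correlation), with Pax5 up 161-fold (adjusted p = 7.29e-11), Cd22 210-fold (adjusted p = 3.8e-10) and Cd74 25.1-fold to 77.8 ± 8.05 CPM (adjusted p = 2.07e-09). Of 40 cell cycle genes 22 rose and 9 fell (adjusted p = 0.0533), with Mki67 up 20.8-fold (adjusted p = 2.07e-11). Of 44 interferon-stimulated genes 21 fell and 10 rose (adjusted p = 0.0744), with Ifit1 down 2-fold (adjusted p = 0.0109). In the plasma cell list 6 of 12 rose (adjusted p = 0.0836), of 14 Sle interval candidates 7 rose and 5 fell (adjusted p = 0.358), and of 22 immediate early genes 8 rose and 5 fell (adjusted p = 0.498).

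Over all genes in TC, 8890 changed, 4535 up and 4355 down, and 11 of 32 list tests passed, 7 up and 4 down. Libraries did not overlap for 9575 genes (71.3%), where chance gives 10%. The call on nuclear oxidative phosphorylation reversed in sign with length correction over all genes (adjusted p = 0.782) and ended with the same correction on genes of at least 5 CPM (adjusted p = 0.944), and that on the TCA list ended with length and GC correction (adjusted p = 0.0666).

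Between strains, the Tfh against Tn changes correlated at Pearson 0.947 and Spearman 0.916. Both comparisons shared 4143 rises and 3732 falls, against 1680 and 1456 if the calls were independent, and 30 genes moved in opposite directions.

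Comparing TC with B6 in Tfh cells, Il10 and Il4 were higher, and Ldha and Slc1a5 lower. Il10 rose 4.83-fold, from 3.14 ± 0.973 to 15.3 ± 6.27 CPM (log2 fold change 2.27, SE 0.28, adjusted p = 3.97e-06), and Il4 1.9-fold (adjusted p = 4.99e-05). Il21 rose 1.31-fold (adjusted p = 0.00285), Ifng 1.48-fold (adjusted p = 0.00291) and Bcl6 1.31-fold (adjusted p = 0.00662). Ldha fell 2.08-fold, from 402 ± 36.2 to 194 ± 15.4 CPM (log2 fold change −1.05, SE 0.079, adjusted p = 3.37e-08), and the glutamine transporter Slc1a5 2.38-fold, from 322 ± 23.1 to 136 ± 4.99 CPM (log2 fold change −1.25, SE 0.10, adjusted p = 2.33e-07). Ldha and Slc1a5 lie on chromosome 7, which carries an Sle interval, and their place relative to it was not examined. Cxcr5 fell 1.5-fold (adjusted p = 0.000931), Ccr7 1.63-fold (adjusted p = 7.58e-05) and Pdcd1 1.4-fold (adjusted p = 0.0098).

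**Figure D2:**
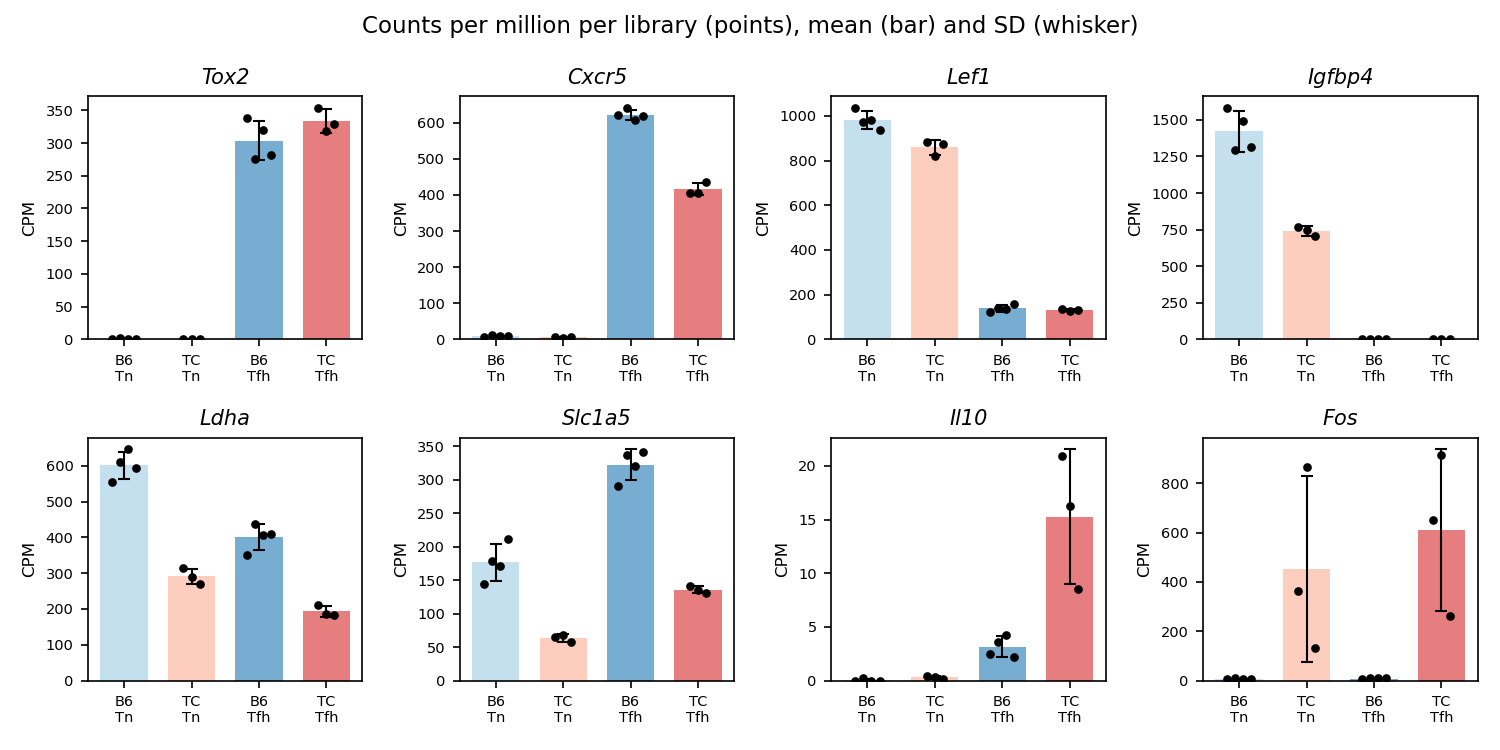
Expression of 8 genes in the 4 groups, in CPM. Points are single libraries, bars means and whiskers SD.

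Lists of helper and other T cell programmes did not pass. Of 27 Tfh identity genes 7 rose and 7 fell (adjusted p = 0.809), of 28 naive genes 5 rose and 5 fell (4 and 5 over the list alone; adjusted p = 0.968), of 18 Treg and Tfr genes 4 rose and 4 fell (4 and 3; adjusted p = 0.958), and of 18 inhibitory receptor genes 6 rose and 5 fell (adjusted p = 0.674). Of 22 Th1 genes 2 rose and 8 fell (adjusted p = 0.383), of 6 Th2 genes 2 rose and 2 fell (adjusted p = 0.704), and of 7 Th17 genes 1 rose and 1 fell (1 and 0; adjusted p = 0.999). Medians of the Tfh identity, Treg and inhibitory receptor lists were below 0 and their means above. Icos (adjusted p = 0.453), Foxp3 (0.767), Cd44 (0.119) and Mki67 (0.367) did not pass. Selplg fell 1.27-fold (adjusted p = 0.0319), but not without B6 Tfh 2 (0.105), B6 Tfh 4 (0.0888) or TC Tfh 4 (0.163).

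Glycolysis genes fell in TC Tfh: 18 of 27 fell and 2 rose (18 and 3 over the list alone; median −0.33, adjusted p = 0.00316, and adjusted p = 0.403 with an estimated correlation). Besides Ldha, they included Gpi1 (1.54-fold, from 434 ± 33.3 to 282 ± 10.9 CPM, adjusted p = 5.87e-07), Pgk1 (1.57-fold, adjusted p = 5.13e-06), the lactate transporter Slc16a1 (1.43-fold, adjusted p = 1.45e-05) and Hk2 (1.64-fold, adjusted p = 0.00258). Slc2a1 fell 1.23-fold (adjusted p = 0.0141), but not without B6 Tfh 3 (0.0561), TC Tfh 2 (0.086) or TC Tfh 4 (0.0551). In the pentose phosphate list 7 of 10 fell (median −0.28, adjusted p = 0.00316, and adjusted p = 0.367 with an estimated correlation), Pgls 1.44-fold (adjusted p = 3.05e-06) and Tkt 1.39-fold (adjusted p = 3.75e-06) among them. Of 18 glutamine and glutamate genes 4 rose and 5 fell (adjusted p = 0.642) and of 26 amino acid transport and mTORC1 genes 5 rose and 13 fell (adjusted p = 0.329).

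Mitochondrial genes encoded in the nucleus were lower in TC Tfh. In the nuclear oxidative phosphorylation list 66 of 72 fell and none rose (67 and 1 over the list alone; median −0.42, adjusted p = 7.5e-17, and adjusted p = 0.403 with an estimated correlation). Ndufs5, a complex I subunit, fell 16.7-fold, from 6.21 ± 0.582 to 0.363 ± 0.0599 CPM (adjusted p = 5.31e-10), Uqcr10 of complex III 1.54-fold (adjusted p = 1.18e-06) and Atp5o of ATP synthase 1.43-fold (adjusted p = 1.66e-06). The fall of Ndufs5 was far wider than the list median, and TC counts were not corrected for alignment to the B6 reference. In the TCA list 17 of 25 fell (median −0.25, adjusted p = 0.000152, and adjusted p = 0.403 with an estimated correlation), with Mdh1 down 1.59-fold (adjusted p = 1.83e-08) and Sdhb 1.38-fold (adjusted p = 6.88e-06). In the fatty acid oxidation list 15 of 23 fell (15, with 1 rise, over the list alone; median −0.26, adjusted p = 0.00316, and adjusted p = 0.403 with an estimated correlation), including Acaa2 (1.54-fold, adjusted p = 2.99e-06), Slc25a20, which carries acylcarnitines into mitochondria (1.59-fold, adjusted p = 5.01e-06), and Acadvl (1.33-fold, adjusted p = 1.91e-05). Of 7 mitochondrial genome genes 2 fell (adjusted p = 0.415).

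Over all protein-coding genes with a length, the strain difference in Tfh moved with transcript length. Log2 fold change correlated with length at Spearman 0.351 over 11638 genes, and its median ran from −0.36 in the decile of shortest transcripts (median 1107 bases) to 0.20 in the longest (8272 bases). In Tn the correlation was 0.268, and between Tfh and Tn it was 0.0195 in B6 and 0.0415 in TC. The lower ribosomal protein share and the higher Gm26917 share of TC libraries followed the same strain division.

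**Figure D3:**
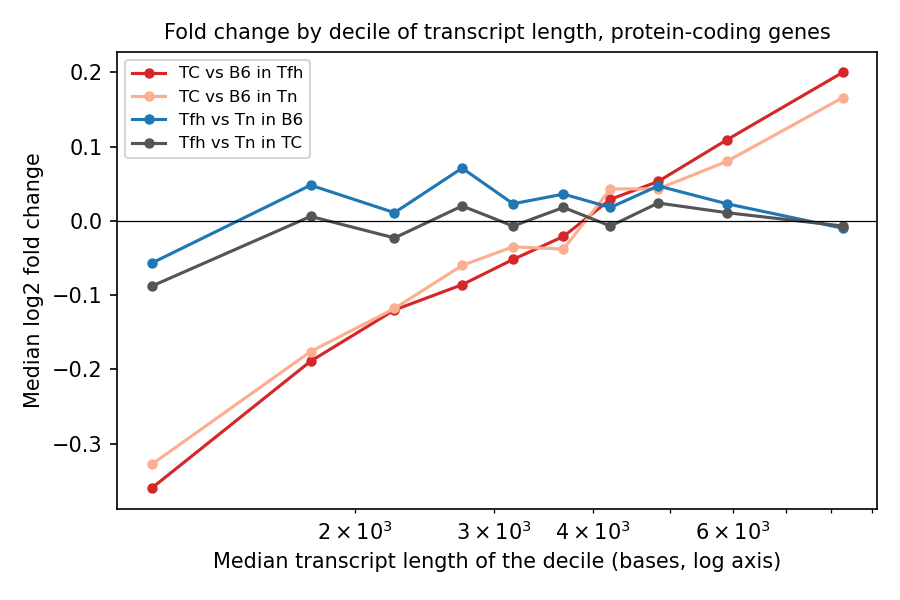
Median log2 fold change in 10 classes of transcript length, for Tfh against Tn in both strains and TC against B6 in both cell types.

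Biosynthesis, cell cycle and senescence lists were lower too. In the one-carbon and nucleotide list 12 of 23 fell (median −0.22, adjusted p = 0.00496, and adjusted p = 0.367 with an estimated correlation), with the mitochondrial folate enzyme Mthfd2 down 1.34-fold (adjusted p = 6.94e-05) and Impdh2 1.24-fold (adjusted p = 8.2e-05). Of 40 cell cycle genes 26 fell and 1 rose (27 and 1 over the list alone; median −0.42, adjusted p = 0.00102, and adjusted p = 0.269 with an estimated correlation), including Mcm2 (1.42-fold, adjusted p = 3.35e-07), the spindle checkpoint kinase Bub1b (3.06-fold, adjusted p = 0.000286) and Ube2c (2.89-fold, adjusted p = 0.000268). Of 15 senescence genes 8 fell and 1 rose (median −0.62, adjusted p = 0.026, and adjusted p = 0.269 with an estimated correlation), among them Cdkn2c (2.25-fold, adjusted p = 2.1e-07), Cdkn2b (2.61-fold, adjusted p = 5.16e-05), Cebpa (1.67-fold, adjusted p = 5.75e-05) and Lgals1 (1.54-fold, adjusted p = 8.23e-05). Cdkn2c is also a member of the list of Sle interval candidates, and it was lower in TC Tn as well. Of 30 fatty acid and cholesterol synthesis genes 9 fell and 2 rose (adjusted p = 0.0731).

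Immediate early genes rose in TC Tfh. In that list 11 of 22 rose and 1 fell (median 0.50, adjusted p = 0.00249, and adjusted p = 0.496 with an estimated correlation). Fos rose 75.5-fold, from 8.07 ± 0.873 to 610 ± 329 CPM (adjusted p = 3.92e-05), Jun 79.8-fold to 284 ± 135 CPM (adjusted p = 2.93e-06), Fosb 57.9-fold to 255 ± 211 CPM (adjusted p = 0.000981), Dusp1 11.5-fold (adjusted p = 1.79e-05) and Zfp36 1.71-fold (adjusted p = 4.46e-05). Their spread over the TC libraries was wide, as the SDs show.

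Plasma cell and monocyte genes were lower in TC Tfh. These lists mark other cells that the gates could hold. Whether fewer such cells or lower expression in Tfh cells lay behind this was not tested. In the plasma cell list 8 of 12 fell (9 over the list alone; adjusted p = 0.0355, and adjusted p = 0.403 with an estimated correlation), including Jchain (3.91-fold, from 10.2 ± 5.08 to 2.63 ± 0.891 CPM, adjusted p = 0.0053), Ighg2b (23.4-fold, adjusted p = 0.00503) and Iglc2 (4.38-fold, adjusted p = 0.0025), whose counts are uncertain because constant-region genes share sequence. Of 7 monocyte and macrophage genes 5 fell (adjusted p = 0.0374, and adjusted p = 0.367 with an estimated correlation), with Lyz2 down 60.6-fold (adjusted p = 0.000418), the protease Ctss 1.54-fold to 178 ± 6.51 CPM (adjusted p = 3.8e-06) and Ccr2 2.78-fold (adjusted p = 0.00481). Of 13 B cell genes 2 rose and 3 fell (1 and 3 over the list alone; adjusted p = 0.674). Of 44 interferon-stimulated genes 14 fell and 5 rose (adjusted p = 0.106). Ifit1 fell 1.7-fold (adjusted p = 0.0426), but not without B6 Tfh 1 (0.0527), 2 (0.12) or 4 (0.0754), or TC Tfh 1 (0.055), 2 (0.152) or 4 (0.0806).

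Single genes with the widest strain differences in Tfh lay on several chromosomes. Eps8l1 (chromosome 7, 4460674 to 4480487) fell 552-fold, from 57.0 ± 6.82 to 0.103 ± 0.133 CPM (log2 fold change −9.11, adjusted p = 5.48e-09), Htatip2 (chromosome 7) 61-fold (adjusted p = 1.04e-14), the tyrosine phosphatase Ptpn5 (chromosome 7) 35.5-fold (adjusted p = 5.95e-14) and Bcam (chromosome 7) 8.8-fold (adjusted p = 3.58e-10). Tceanc2 (chromosome 4) fell 14.4-fold (adjusted p = 9.08e-15) and Rasgrf2 (chromosome 13) 10.2-fold (adjusted p = 1.13e-07). Cyp4f18 (chromosome 8) rose 397-fold to 48.9 ± 32.8 CPM (adjusted p = 2.03e-08), Adgra2 (chromosome 8, 27085583 to 27123436) 287-fold to 24.2 ± 4.68 CPM (adjusted p = 1.67e-15) and Mtus1 (chromosome 8, 40990914 to 41133726) 137-fold to 83.6 ± 2.21 CPM (adjusted p = 8.78e-20). Jak3 (chromosome 8), a kinase of common gamma chain receptors, rose 2.08-fold to 948 ± 30.2 CPM (adjusted p = 4.43e-10), and Gzma (chromosome 13), encoding granzyme A, 5.91-fold (adjusted p = 3.35e-07). Among 14 Sle interval candidates 6 rose and 5 fell (adjusted p = 0.704): the SLAM family genes of chromosome 1 Cd84 (1.4-fold, adjusted p = 1.68e-06) and Slamf6 (1.42-fold, adjusted p = 2.04e-05) rose and Cd48 fell 1.73-fold (adjusted p = 3.7e-09). Other counts over the list alone were the same in this comparison.

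Over all genes 6803 differed between TC and B6 Tfh, 3323 up and 3480 down, and 11 of 32 list tests passed, 1 up and 10 down. Libraries did not overlap for 6742 genes (50.2%), where chance gives 5.71%. With transcript length correction, chosen after seeing the data, the calls on Ifit1 (adjusted p 0.0523 to 0.0605) and Selplg (0.0627 to 0.109) ended in all 3 forms and Cd44 passed (0.00468 to 0.0104); on genes of at least 5 CPM those on senescence (0.0503) and Pdcd1 (0.0562) also ended, and with GC those on plasma cell and monocyte genes (0.0505 each). All TC libraries are of other mice than the B6 libraries, and sequencing batch is not in the labels.

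In naive cells TC and B6 differed in many of the same genes. Ldha fell 2.06-fold, from 601 ± 38.3 to 291 ± 21.6 CPM (log2 fold change −1.04, SE 0.079, adjusted p = 2.22e-08), and Slc1a5 2.78-fold, from 176 ± 27.4 to 63.4 ± 5.34 CPM (log2 fold change −1.48, SE 0.10, adjusted p = 3.87e-08). Fos rose 64.9-fold to 453 ± 377 CPM (adjusted p = 3.95e-05) and Jun 41-fold to 372 ± 181 CPM (adjusted p = 2.87e-06). Gzma rose 45.9-fold to 29.7 ± 3.93 CPM (adjusted p = 2.02e-12) and Jak3 2.04-fold (adjusted p = 5.59e-10), while Cdkn2c fell 11.9-fold to 0.329 ± 0.00931 CPM (adjusted p = 3.11e-08).

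Of the glycolysis list 13 of 27 fell and 4 rose (median −0.31, adjusted p = 0.0146, and adjusted p = 0.697 with an estimated correlation), including Slc16a1 (1.85-fold, adjusted p = 1.92e-08), Gpi1 (1.59-fold, adjusted p = 1.76e-07) and Pdk1 (1.85-fold, from 512 ± 16.7 to 276 ± 35.8 CPM, adjusted p = 7.72e-07). Of the pentose phosphate list 9 of 10 fell (median −0.37, adjusted p = 0.000443, and adjusted p = 0.514 with an estimated correlation), with Pgls down 1.55-fold (adjusted p = 2.69e-07) and Rpe 1.47-fold (adjusted p = 3.17e-06). Slc2a1 (adjusted p = 0.312) and Hk2 (0.484) did not pass. Of 18 glutamine and glutamate genes 3 rose and 7 fell (adjusted p = 0.209), and of 26 amino acid transport and mTORC1 genes 6 rose and 9 fell (adjusted p = 0.443).

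Mitochondrial genes were lower in TC Tn. Among them the fall of Ndufs5 was far wider than the median of its list, as in Tfh. In the nuclear oxidative phosphorylation list 63 of 72 fell and 1 rose (65 and 1 over the list alone; median −0.45, adjusted p = 6.99e-16, and adjusted p = 0.697 with an estimated correlation), with Ndufs5 down 29-fold (adjusted p = 1.16e-10), Ndufa8 1.74-fold (adjusted p = 2.77e-07) and Atp5o 1.5-fold (adjusted p = 2.69e-07). In the TCA list 15 of 25 fell and 1 rose (median −0.26, adjusted p = 0.000266, and adjusted p = 0.697 with an estimated correlation), with Mdh1 down 1.69-fold (adjusted p = 3.02e-09) and Sdha 1.32-fold (adjusted p = 1.12e-06). All 7 mitochondrial genome genes fell (median −0.64, adjusted p = 0.00994, and adjusted p = 0.697 with an estimated correlation), mt-Nd1 1.73-fold, from 2521 ± 339 to 1456 ± 68.6 CPM (adjusted p = 2.5e-06), and mt-Cytb 1.55-fold (adjusted p = 0.000167). In the fatty acid oxidation list 12 of 23 fell and 3 rose (median −0.21, adjusted p = 0.0133, and adjusted p = 0.697 with an estimated correlation), with Acaa2 down 1.7-fold (adjusted p = 9.72e-08) and Hadhb 1.44-fold (adjusted p = 9.45e-07). In the one-carbon and nucleotide list 14 of 23 fell and 2 rose (15 and 2 over the list alone; median −0.28, adjusted p = 0.00732, and adjusted p = 0.514 with an estimated correlation), with Impdh2 down 1.35-fold (adjusted p = 1.45e-06) and Paics 1.33-fold (adjusted p = 2.17e-06). Of 30 fatty acid and cholesterol synthesis genes 5 rose and 6 fell (adjusted p = 0.987), and of 40 cell cycle genes 4 rose and 11 fell (4 and 10; adjusted p = 0.408).

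Of 22 immediate early genes in Tn 11 rose and 1 fell (median 0.51, adjusted p = 0.0399, and adjusted p = 0.726 with an estimated correlation), with Junb up 6.57-fold to 929 ± 348 CPM (adjusted p = 9.01e-06) and Dusp1 11.1-fold (adjusted p = 2.66e-05). Helper and regulatory lists did not pass: of 27 Tfh identity genes 4 rose and 5 fell (3 and 5 over the list alone; adjusted p = 0.77), of 28 naive genes 4 rose and 8 fell (adjusted p = 0.559), of 18 Treg and Tfr genes 1 rose and 8 fell (adjusted p = 0.209), of 22 Th1 genes 1 rose and 5 fell (1 and 4; adjusted p = 0.77) and of 18 inhibitory receptor genes 4 rose and 3 fell (adjusted p = 0.704). Of 6 Th2 genes 2 fell (adjusted p = 0.559), of 7 Th17 genes 1 rose (adjusted p = 0.77), and of 15 senescence genes 3 fell (adjusted p = 0.559). Cxcr5 fell 1.84-fold (adjusted p = 0.00259), Ccr7 1.3-fold (adjusted p = 0.00413) and Cd44 1.38-fold (adjusted p = 0.000303). Bcl6 (adjusted p = 0.221), Il21 (0.081), Il4 (0.074), Icos (0.115), Ifng (0.385), Il10 (0.254), Mki67 (0.488) and Pdcd1 (0.0736) did not pass, but Il21 (0.037) and Il4 (0.0469) did without TC Tn 2. With DESeq2 Il21 (0.0163), Il4 (0.0219), Il10 (0.0191) and Pdcd1 (0.0238) passed, with legacy quasi-likelihood Il4 (0.0181), and with only the groups compared Icos (0.0309) and Pdcd1 (0.028).

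Foxp3 fell 1.45-fold in TC Tn (adjusted p = 0.0169), but not without TC Tn 2 (0.0633) or TC Tn 4 (0.0598). Ifit1 fell 1.73-fold (adjusted p = 0.0201), but not without TC Tn 2 (0.0807), and of 44 interferon-stimulated genes 17 fell and 7 rose (adjusted p = 0.117). Selplg fell 1.29-fold (adjusted p = 0.0192), but not without B6 Tn 3 (0.055), TC Tn 2 (0.0546) or TC Tn 4 (0.0648). Of 13 B cell genes 4 fell (adjusted p = 0.366), including Cd74 (4.26-fold, from 13.2 ± 3.75 to 3.09 ± 0.829 CPM, adjusted p = 3.79e-05) and H2-Aa (16.5-fold, adjusted p = 0.00153). Of 12 plasma cell genes 2 fell (1 over the list alone; adjusted p = 0.704), and of 7 monocyte genes 1 rose and 3 fell (adjusted p = 0.318). Other counts over the list alone were the same in this comparison.

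Several wide strain differences recurred in Tn. Mtus1 rose 1720-fold to 157 ± 3.28 CPM (log2 fold change 10.75, SE 0.14, adjusted p = 3.01e-21). Adgra2, with 3 counts in B6 Tn, all in B6 Tn 1, rose to 22.4 ± 3.51 CPM, a ratio of 534 (95% counting interval 183 to 2590, adjusted p = 3.18e-15), and Cyp4f18, also with 3, to 18.4 ± 6.42 CPM, a ratio of 439 (150 to 2130, adjusted p = 6.85e-07). Irgc1 (chromosome 7) rose 112-fold to 46.1 ± 4.49 CPM (adjusted p = 1.02e-14) and Syt14 (chromosome 1, 192891233 to 193035775) 80.9-fold (adjusted p = 3.6e-12). Eps8l1 fell 244-fold (adjusted p = 3.53e-08), Htatip2 185-fold (adjusted p = 4.24e-14), Nav2 (chromosome 7) 63.2-fold, from 31.0 ± 5.69 CPM (adjusted p = 3.53e-08), the BH3-only gene Bmf (chromosome 2) 34.2-fold (adjusted p = 0.000896), Raver2 (chromosome 4) 14.8-fold (adjusted p = 5.68e-09) and Tceanc2 13.4-fold (adjusted p = 5.79e-15). Of 14 Sle interval candidates 6 rose and 3 fell (adjusted p = 0.66), with Cd84 up 1.6-fold (adjusted p = 3.36e-08) and Cd48 down 1.49-fold (adjusted p = 9.96e-08).

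Over all genes 6962 differed between TC and B6 Tn, 3460 up and 3502 down, and 8 of 32 list tests passed, 1 up and 7 down. Libraries did not overlap for 7455 genes (55.5%), where chance gives 5.71%. With transcript length correction on genes of at least 5 CPM the calls on fatty acid oxidation (adjusted p = 0.0504) and mitochondrial genome genes (0.0607) ended, and with GC added also that on immediate early genes (0.0557).

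Strain changes in Tfh and Tn correlated at Pearson 0.687 and Spearman 0.724. Both shared 2465 rises and 2615 falls, against 856 and 908 if independent, and 47 genes moved in opposite directions. Both comparisons come from the same 7 mice and share a length trend, which the values for independence leave out. Genes called the same way in both cell types were more frequent on chromosome 7 (odds ratio 1.42, adjusted p = 2.84e-06), where Ldha, Gpi1, Slc1a5, Eps8l1 and Htatip2 lie. Among genes past 2-fold in both, chromosome 7 (odds ratio 2.35, adjusted p = 1.89e-07) and chromosome 1 (2.18, adjusted p = 1.66e-05) were enriched and chromosome 4 was not (1.01, adjusted p = 0.918).

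The strain by cell type interaction asks whether the Tfh against Tn change differed between TC and B6. It was called for 282 genes in the main fit, without mouse as a block, and for 712 with it. The Tfh to Tn ratio of Cdkn2c was 5.28-fold larger in TC (log2 difference 2.40, SE 0.33, adjusted p = 0.000446). Its level was lower in TC than in B6 in both cell types, and near the floor in TC Tn. The fall of Igfbp4 was 3.03-fold smaller in TC (adjusted p = 0.000214), its Tn level being 1422 ± 139 CPM in B6 and 741 ± 31.5 in TC. Bcl2, the survival gene, fell from 335 ± 35.9 CPM in Tn to 145 ± 20.7 in Tfh in B6, and in TC stood at 177 ± 12.5 and 152 ± 18.2, a 1.98-fold difference (adjusted p = 0.00391). The Tfh against Tn difference of Gpr83, a receptor of regulatory T cells, was 1.81-fold larger in TC (adjusted p = 0.0055), and that of Ccne1, encoding cyclin E1, 2.07-fold (adjusted p = 0.015).

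Among the widest interactions, the Tfh to Tn ratio was higher in TC for Nav2 (12.6-fold, adjusted p = 0.00087) and Pglyrp1 (7.42-fold, adjusted p = 1.79e-06). The same held for Igsf23 (6.15-fold, adjusted p = 3.06e-08), Arsb (5.22-fold, adjusted p = 3.14e-08) and Myo6 (5.21-fold, adjusted p = 1.79e-06). The ratio was lower in TC for Mtus1 (12.6-fold, adjusted p = 2.47e-05), Sec16b (11.7-fold, adjusted p = 1.52e-05) and Lsr (8.01-fold, adjusted p = 0.000191). So it was for Gzma (7.76-fold, adjusted p = 0.000406) and Lmtk3 (7.59-fold, adjusted p = 5.87e-05). These folds compare ratios and not levels: Nav2 was lower in TC Tn, and Mtus1 and Gzma were higher in TC in both cell types. In B6 Tn Mtus1 was near the floor, at 0 to 0.117 CPM. For Ptpn5 the ratio was 61.5-fold lower in TC (adjusted p = 0.0141), but not called without TC Tn 1 (0.0616), TC Tn 2 (0.0737) or TC Tn 4 (0.0602).

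Of the lists, mitochondrial genome genes shifted up in the interaction (median 0.49, 1 of 7 called, 6 over the list alone; adjusted p = 0.0034, and adjusted p = 0.611 with an estimated correlation), as did Treg and Tfr genes (2 of 18 called up, the same over the list alone; adjusted p = 0.0174, and adjusted p = 0.611 with an estimated correlation). Fatty acid and cholesterol synthesis genes shifted down (4 of 30 called down; 7 down and 2 up over the list alone; median −0.19, adjusted p = 0.0174, and adjusted p = 0.611 with an estimated correlation), as did cell cycle genes (2 up and 4 down of 40; 3 and 6 over the list alone; median −0.17, adjusted p = 0.0174, and adjusted p = 0.611 with an estimated correlation). Plasma cell genes (none of 12 called; 2 down over the list alone) gave adjusted p = 0.05, not below the threshold, and 0.0255 with mouse as a block. The Th2 list (none of 6 called) gave adjusted p = 0.0549, and 0.0285 with mouse as a block. Nuclear oxidative phosphorylation (none of 72 called, adjusted p = 0.356) and glycolysis (none of 27 called, 3 up over the list alone; adjusted p = 0.91) did not pass.

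Other helper and metabolic markers did not pass the interaction test: Cxcr5 (adjusted p = 0.661), Bcl6 (0.644), Il21 (0.51), Il10 (1), Ifng (0.877), Icos (0.368, and 0.0197 with mouse as a block), Foxp3 (0.229), Ldha (0.997), Hk2 (0.847) and Slc2a1 (0.612). In total 282 genes passed, 116 up and 166 down, where 1903 had an unadjusted p below 0.05, and 4 of 32 list tests passed. The excess of falls was not stable: 269 were up and 266 down with DESeq2, and 144 and 120 without TC Tfh 2, but 80 and 214 with no filter. With mouse as a block 712 genes passed. Leaving out single libraries moved the count by more than 1.5 times without B6 Tn 2 (186), B6 Tn 3 (182), TC Tfh 1 (182), TC Tfh 4 (155), TC Tn 1 (178) and TC Tn 2 (137).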

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

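The tests in this part were chosen after the results were seen, apart from the other divisions of the libraries, the interaction and the leaving out of single libraries. The first pattern weighed is the lower level of nuclear oxidative phosphorylation genes in TC, against a trend with transcript length. The list's median log2 fold change was −0.412 in Tfh and −0.449 in Tn, where lists matched in length and expression had medians of −0.328 (95% of lists −0.393 to −0.24) and −0.315 (−0.391 to −0.229). It ranked at percentile 0.44 and 0.03 of 10000 such lists, though matched lists carried 79.8% and 70% of the shift. Genes of the matched lists were drawn singly, while those of this list vary together (estimated correlation 0.51). The percentiles therefore overstate the evidence. Length was matched by decile only, so length as the whole cause is not excluded. Separate preparation of TC and B6 libraries remains open, since 6 of 6 TC libraries had a Gm26917 share above every B6 library, and strain and preparation cannot be told apart here. As a biological hypothesis, a strain effect on mitochondrial genes could account for the part beyond the matched lists. Measured against lists matched in the same way within each library, the TC mean lay from the B6 mean by −0.1 in Tfh and −0.126 in Tn. Every TC library lay below every B6 library (exact permutation p = 0.0286 in each cell type, the lowest that 35 divisions allow).

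The second is the higher level of immediate early genes in TC, weighed against handling of the spleens and acute T cell receptor stimulation. Fos was above every B6 library in 6 of 6 TC libraries, which handling predicts as well as strain does, so handling remains open. Receptor stimulation predicts a rise of Egr1, Egr2, Egr3, Nr4a1 and Nr4a3, and the highest upper 95% limit of their log2 fold changes was 0.679 (Nr4a1 in Tfh), against 6.24 for Fos, which speaks against it as the whole cause. In Tfh Nr4a1 (0.44, adjusted p = 0.00736) and Egr1 (0.17, adjusted p = 0.0489) did rise, so a smaller part stays open there, while in Tn Egr2 (−0.67, adjusted p = 1.51e-05) and Nr4a3 (−0.55, adjusted p = 0.0046) fell. A strain effect on these genes, as a biological hypothesis, was not separated from handling by any test here.

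The third is the higher level of Ighm in Tfh than in Tn, weighed against B cells in the Tfh sort. B cells would raise Cd79a with Ighm, and the upper 95% limits of the Cd79a log2 fold change were 0.974 in B6 and 0.826 in TC, under the lower limits for Ighm of 1.403 and 1.132. With a mean of 0.503 CPM, though, Cd79a is near the floor and excludes nothing. Cd79b rose (log2 fold change 2.62 in B6 and 3.58 in TC), as did 12 of 13 B cell markers in B6 and 11 in TC, so B cells remain open. Expression of these genes by Tfh themselves, as a biological hypothesis, was not tested.

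Other divisions of the libraries were refitted and their called genes counted. These divisions mix libraries of the real groups, so the real difference widens the spread within groups and lowers the calls. Their counts therefore do not show how many genes chance alone would call. Between Tfh and Tn in B6, 1 of 35 divisions (the real 1) called as many as the real 8870, and the highest other called 0, also among the 8 that part as many mouse pairs. In TC 1 of 10 divisions called as many, which are too few to judge by. Between strains in Tfh it was 1 of 35 (real 6011, highest other 1), and in Tn 1 of 35 (real 7130, highest other 2802). For the interaction 1 of 35 divisions of the 7 mice called as many (real 282, highest other 0).

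Of 280 groups of 4 libraries, 12 had a library far from the others (Dixon ratio above 0.829), where chance flags about 1 in 20. In B6 Tfh these were Adgra2, at 0 CPM in library 2 against 0.101 to 0.105, Arsb, at 42.2 in library 3 against 36 to 36.8, and the total of library 2, 19282023 counts against 18547283 to 18646860. In B6 Tn library 2 they were Ecel1 (0.0578 CPM against 0), Kif15 (0.81 against 0.393 to 0.464), Ifit2 (102 against 108 to 109) and Il10 (0.231 against 0). In B6 Tn library 1 they were Ampd1 (35.6 against 24.8 to 25.6), Mtus1 (0 against 0.112 to 0.117), Adgra2 (0.155 against 0) and Syt14 (0.309 against 0.0562 to 0.0585), and in library 4 Htatip2 (17.5 against 19.6 to 19.8).

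The Tfh against Tn change differed between strains for 282 genes by the interaction test. Log2 differences were 3.66 for Nav2, 2.89 for Pglyrp1, 2.62 for Igsf23, 2.40 for Cdkn2c, 2.38 for Arsb, 2.38 for Myo6, 1.60 for Igfbp4, 1.05 for Ccne1, 0.99 for Bcl2 and 0.86 for Gpr83. They were −3.65 for Mtus1, −3.54 for Sec16b, −3 for Lsr, −2.96 for Gzma, −2.92 for Lmtk3 and −0.95 for Sqle. Ptpn5 (−5.94) was not called without TC Tn 1 (adjusted p = 0.0616), 2 (0.0737) or 4 (0.0602).

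For other genes with a called interaction the call also rested on single libraries. These adjusted p, without each library, come from the fit without mouse as a block. Cd74 (1.64): TC Tn 2 (0.0793), 4 (0.0735). Klrd1 (−2.51): B6 Tfh 2 (0.0677), TC Tfh 1 (0.072), 4 (0.089). Cyp51 (−0.54): TC Tfh 1 (0.0773), 4 (0.0843), TC Tn 2 (0.0645). Cdc20 (−0.93): TC Tfh 1 (0.0637), 4 (0.0673), TC Tn 1 (0.0616), 4 (0.0575). Mcm2 (0.28): B6 Tfh 3 (0.0524), B6 Tn 2 (0.0818), 3 (0.0688), TC Tfh 4 (0.081), TC Tn 1 (0.0587), 2 (0.122), 4 (0.0503). Lss (−0.49): B6 Tfh 1 (0.0631), 2 (0.0506), B6 Tn 1 (0.0524), 2 (0.0578), 3 (0.0624), TC Tfh 1 (0.0881), 2 (0.0633), 4 (0.0815), TC Tn 2 (0.0763). Ube2c (−2.70): B6 Tfh 4 (0.0589), B6 Tn 1 (0.0786), 3 (0.0759), 4 (0.0715), TC Tfh 1 (0.0783), 2 (0.0549), TC Tn 1 (0.0925), 2 (0.122), 4 (0.0862). Capg (0.74): B6 Tfh 1 (0.0633), 2 (0.0557), B6 Tn 1 (0.0805), 2 (0.0751), 3 (0.0759), TC Tfh 1 (0.0773), 4 (0.081), TC Tn 1 (0.0936), 2 (0.133), 4 (0.0503). Fads1 (−0.43): B6 Tfh 1 (0.0701), 2 (0.0611), 4 (0.0915), B6 Tn 1 (0.0802), 2 (0.056), 3 (0.0808), 4 (0.0522), TC Tfh 2 (0.104), 4 (0.138), TC Tn 1 (0.115), 2 (0.106), 4 (0.0514). mt-Nd1 (0.53): B6 Tfh 1 (0.0522), 3 (0.0701), 4 (0.051), B6 Tn 2 (0.0901), 3 (0.085), 4 (0.0696), TC Tfh 1 (0.0916), 2 (0.0567), 4 (0.0689), TC Tn 1 (0.0706), 2 (0.0931), 4 (0.107).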

How the results depend on the processing

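Counts of changed genes kept within 1.5 times for Tfh against Tn in B6 (8109 with a count minimum of 50 to 10064 with no filter), in TC (7660 to 9473), and for TC against B6 in Tfh (5103 to 6803) and Tn (6031 to 7130), except with a fold above 2: 3596, 3553, 903 and 1031, and 92 for the interaction. Leaving out 1 library gave 9029 to 9331, 8322 to 8536, 5999 to 6695, 6031 to 6805 and, for the interaction, 137 to 299. The interaction count rose from 282 to 535 with DESeq2, 568 with voom and 712 with mouse as a block; the cause was not tested. List tests past the threshold fell from 15, 11, 11, 8 and 4 to 2, 2, 0, 0 and 0 with an estimated correlation, and with fry, which tests lists against no change rather than against other genes, became 31, 31, 16, 20 and 0. With length and GC correction, chosen after seeing the data, 5 lists passed for TC against B6 in Tn. Nuclear oxidative phosphorylation in Tfh against Tn in TC reversed with length correction on all genes (adjusted p = 0.782) and with length and GC correction (0.95); the cause was not tested.

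Between TC and B6, libraries with the same number come from different mice (correlations −0.063 to 0.106). A fit with the number as a block also left out the other groups and library 3 of B6, which has no TC partner, and tested 12818 and 11861 genes. It gave 5103 calls in Tfh and 6233 in Tn, where only the groups compared gave 6011 and 7130 without it; the part due to the block alone was not tested. With the same libraries and block in Tfh, cholesterol synthesis (adjusted p = 0.0197), interferon-stimulated (0.00767) and chemokine receptor (0.0134) lists passed, and Ifng (0.0676) and Slc2a1 (0.121) did not; in Tn, mitochondrial genome (0.069) and immediate early (0.0689) lists did not pass. With mouse as a block Tfh against Tn gave 9916 calls in B6 and 9397 in TC, and in the interaction Icos (0.0197), mt-Nd2 (0.00692) and mt-Cytb (0.0175) passed. The block changed no other call on a list or on a gene named in the text beside those in the report.

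Agreement of the Tfh against Tn change between strains was 0.964 with a count minimum of 50 and 0.942 to 0.948 without single libraries, and that of the strain change 0.739 and 0.658 to 0.687. The odds ratio of chromosome 1 rose with a fold above 2 to 2.17 in Tfh, 1.87 in Tn and 2.18 in both (1.09, 0.951 and 1.02 without it). Named genes that were tested kept their calls between Tfh and Tn, apart from a gain of Slc2a1 in B6 without B6 Tfh 1 (adjusted p = 0.0183); a fold above 2 was not applied to named genes. With no filter on low counts, Ifit1 (0.0769) and Selplg (0.0617) were not called between strains in Tfh, nor Foxp3 (0.0515), Ifit1 (0.0516) and Selplg (0.0676) in Tn, nor mt-Nd1 (0.0823), Capg (0.123), Mcm2 (0.187) and Cd74 (0.0578) in the interaction. Selplg was also not called in Tfh with only the groups compared (0.122), nor in Tn with length and GC correction (0.0725). Depth limits genes near the floor of 0.149 to 0.198 CPM.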

Other observations

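Signalling and survival lists moved both ways between Tfh and Tn, and none passed its list test. Among 25 apoptosis genes 15 rose and 6 fell in B6 (adjusted p = 0.177) and 14 rose and 6 fell in TC (0.0836). Among 22 PI3K-AKT and FOXO genes 8 rose and 12 fell in B6 (9 and 12 over the list alone; adjusted p = 0.177) and 6 and 13 in TC (7 and 13; 0.135), with Foxo1 (log2 fold change −1.14 and −1.16) and the PI3K inhibitor Pik3ip1 (−2.29 and −2.35) down. Among 38 TCR signalling genes 20 rose and 11 fell in B6 (adjusted p = 0.177) and 19 and 14 in TC (0.278). Among 32 JAK-STAT genes 14 rose and 13 fell in B6 (15 and 13; adjusted p = 0.971) and 16 and 11 in TC (0.602), with Il4ra down (−2.41 and −2.36) and Il12rb1 up (3.10 and 3.64). Among 20 chemokine receptor and trafficking genes 14 rose and 6 fell in B6 (adjusted p = 0.135) and 12 and 6 in TC (0.152), with the integrin Itgb1 up (4.21 and 3.97) and S1pr1, which guides exit from lymphoid organs, down (−1.70 and −1.95).

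Between strains these lists did not pass either. In Tfh and Tn in turn, apoptosis genes gave 5 up and 10 down (7 and 10 over the list alone; adjusted p = 0.674) and 5 and 9 (6 and 10; 0.366), PI3K-AKT genes 8 and 3 (0.226) and 6 and 1 (0.366), TCR genes 10 and 9 (11 and 9; 0.674) and 10 and 6 (9 and 5; 0.77), JAK-STAT genes 5 and 10 (0.704) and 4 and 10 (0.307), and chemokine receptor genes 0 and 9 (0.0731) and 1 and 4 (0.207). Ikbke rose in both cell types (0.60 and 0.67), and Spry1, a feedback inhibitor of receptor signalling, rose in Tfh (1.55, adjusted p = 1.58e-05). NKT and gamma-delta markers gave 5 of 7 up in B6 Tfh against Tn (adjusted p = 0.161) and 4 in TC (0.217), and dendritic cell markers 3 up and 2 down of 5 in both strains (0.553 and 0.535).

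The positions of genes past 2-fold between TC and B6 in both cell types were examined in windows of 10 megabases, a test chosen after seeing the data. Of 254 windows with at least 10 genes, 7 held more of these 436 genes than the 3.32% found over all (Fisher test, adjusted over windows). On chromosome 1 they were 150 to 160 Mb (8 of 54 genes, adjusted p = 0.0137) and 190 to 200 Mb (7 of 36, 0.00974). On chromosome 7 they were 10 to 20 Mb (12 of 91, 0.00521), 30 to 40 Mb (10 of 81, 0.0137), 40 to 50 Mb (21 of 112, 2.43e-08) and 50 to 60 Mb (5 of 14, 0.00521). On chromosome 14 it was 50 to 60 Mb (18 of 213, 0.0136). T cell receptor segments, left out by the naming rule, were kept in the windows. How many of the genes in the chromosome 14 window are such segments was not counted. No window of chromosome 4 passed.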
